A study of Homo sapiens with 30 samples.

How the data were processed

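Polyadenylated RNA from the RV and LV free walls of 15 human hearts was sequenced as 30 libraries, 5 for each of 6 groups given by heart state (NF, LV-HF and BiV-HF) and ventricle. Per the labels, libraries were made with the NEBNext Ultra kit, and their strandedness is not given in the sources used here. The submitters' processing notes name cutadapt for trimming, HISAT2 for alignment and StringTie for assembly on hg38, and their versions are not given in the sources used here. The deposited table holds counts, which the file headers call raw fragment numbers, for 25826 loci. The deposited table also holds FPKM for the same loci, made by the authors. A header line of the table calls the LV-HF group HF and the BiV-HF group BiVFwPH, which the sources used here do not explain, while its column names have LV-HF and BiV-HF. All count columns best matched the FPKM column of their own library (30 of 30) in their pattern of zeros.

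The genome build of the table is not settled. Of 19084 gene symbols shared with GENCODE release 29 on GRCh38, 754 (3.951%) had a start or end within 1000 bp, which conflicts with the hg38 of the notes. Coordinates are therefore given only as the table has them. Loci were used by the gene symbol that the table gives, and whether the build affected the counts was not tested. Left out were 1801 loci without a gene name (0.446% of fragments) and 125 loci of sex-linked genes, so that 23900 loci remained. Of these, the 1179 on alternative contigs, with 0.0% of fragments, were also left out of the fits. The table has 386 loci of several genes with 1.532% of fragments, and none of the mitochondrially encoded genes, whose list was not analysed here. Near-identical genes such as HBA1 and HBA2, the HLA genes, FCGR3A and FCGR3B share fragments in ways that the table does not resolve.

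Counts were analysed with edgeR 4.0.16 in R 4.3.3. Loci were filtered with filterByExpr, scaled by TMM and fitted with glmQLFit, and the two-sided quasi-likelihood test was used with Benjamini-Hochberg adjustment and a threshold of 0.05. Heart states were compared within a ventricle in 1 fit of 15 libraries. RV and LV, and the interactions of ventricle and heart state, were compared in 1 fit of all 30 libraries. The edgeR test gave every adjusted p of a gene unless another test is named. The choice between tests for counts and for FPKM, the comparisons, the gene lists and most alternatives were fixed before the data were examined. FPKM had been thought the more probable unit, and since counts were present the branch for counts was used.

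WIPI1 was also tested with exact two-sided permutation tests of group means, adjusted over 9 comparisons. In all 47 gene lists had been written, and a list needed 5 measured members. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and beside each the members called are counted over all genes and adjusted over the list alone. WIPI1 was correlated with list scores, the mean of z-scored log values, after removing group means, with 100000 permutations (smallest p possible 1e-05) and adjustment over 88 relations. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

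Genes were named by a rule: WIPI1, the 8 largest rises and the 8 largest falls among called genes with an assigned symbol and a mean CPM of at least 5, and up to 4 members with the smallest p of each list called or counted. Where no gene passed, the 3 smallest p in each direction are given as values. From the lists, the members printed are a choice among those 4. The rule leaves out further genes, and those named outside it are said to be chosen after their values were seen. The search for single distant libraries ran over 16 genes chosen after their values were seen and the fragment totals. Some genes that the rule names are not reported here.

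Equal library numbers in RV and LV were checked to be 1 heart: each of 15 RV libraries matched the LV library of its own number best, and 0 of 15 pairs conflicted in sex-linked genes. Across heart states an equal number had a median r of -0.0435 and is not a pair. The smallest chi-square per locus between any pair of libraries was 6.188, so no library is a copy of another.

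Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors, upper-quartile scaling, no filter on low counts, a CPM of at least 5 in 5 libraries, the replicate number as a block, other sets of libraries in the fit, and each library left out in turn. For lists they were an estimated correlation, fry, the block and the other scalings. Chosen after seeing the data were limma with a trend on log2(FPKM + 1), for loci with at least 1 FPKM in 5 libraries, leaving out NF RV libraries 3 and 4, the WIPI1 level on FPKM and the tests of WIPI1 within hearts (sign flips, and exact permutations between heart states). Tested on simulated data, edgeR found 61 of 100 planted changes of 2-fold and 91 of 99 of 4-fold for BiV-HF against NF in the RV with 11 false calls, and 35 of 100 and 77 of 99 for an interaction with 3 false calls. The simulated libraries were drawn independently, without pairs of RV and LV from 1 heart. The interaction figures therefore do not describe that test on the paired libraries of the data. For the correlations 98 of 100 planted relations were found and 9 of 4500 others called. The planted correlation was 0.9, among 46 independent relations per simulation without groups, where the data have 88 relations. Weaker relations were not simulated, so this gives no power for them.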

Results

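Polyadenylated RNA was sequenced from the free walls of the right ventricle (RV) and the left ventricle (LV) of 15 human hearts. The hearts belonged to 3 states of 5 hearts each: non-failing (NF), left-sided failure (LV-HF) and bi-ventricular failure (BiV-HF), so that the 30 libraries form 6 groups of 5. The series title puts forward WIPI1, a phosphoinositide-binding protein of the autophagy machinery, as a hub of right heart failure. The design sets a failing RV (BiV-HF) against an RV whose heart fails mainly on the left (LV-HF) and an RV without failure. Fragment totals ran from 4.203 M to 9.356 M per library with a median of 6.907 M. Group ranges, also in M, were 4.2 to 8.1 in NF RV, 6.63 to 9.3 in LV-HF RV, 6.49 to 7.06 in BiV-HF RV, 5.46 to 9.36 in NF LV, 5.05 to 8.05 in LV-HF LV and 5.61 to 8.17 in BiV-HF LV. Levels are given in CPM, fragment counts scaled to the library total of the filtered loci times its TMM factor. They are mean ± SD of 5 libraries, and log2 fold changes are estimate ± SE of the edgeR fit. Genes are said to have risen or fallen where the adjusted p was under 0.05. Nuclear-retained transcripts differed in spread between the groups: MALAT1 stood at 2039 ± 1455 CPM in NF RV, 795 ± 160 in LV-HF RV and 871 ± 152 in BiV-HF RV, and NEAT1 at 448 ± 314, 141 ± 24.5 and 138 ± 34.6.

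WIPI1 (locus XLOC_010455, chromosome 17, 66417421 to 66453653 in the coordinates of the file, whose genome build is not settled) was counted with 214 to 752 fragments per library. Its level was 60.9 ± 13.3 CPM in NF RV, 61.3 ± 6.48 in LV-HF RV and 82.7 ± 18.0 in BiV-HF RV. In the LV it was 74.6 ± 13.5 in NF, 69.3 ± 15.6 in LV-HF and 65 ± 7.51 in BiV-HF. The BiV-HF RV mean lay above that of LV-HF RV by 0.43 on the log2 scale (exact two-sided permutation p = 0.0397, adjusted p = 0.214 over 9 comparisons) and above that of NF RV by 0.44 (exact p = 0.0635, adjusted p = 0.214). With 5 against 5 libraries the smallest p possible was 0.00794. RV against LV within BiV-HF hearts gave 0.35 (exact p = 0.0714, adjusted p = 0.214), and the other 6 comparisons had adjusted p of 0.339 or more. None of the 9 differences passed the threshold. A single difference, even at the smallest p possible, could not have passed after adjustment over 9 tests unless another lay as low. The lack of a call is therefore no sign that WIPI1 was unchanged. Within hearts WIPI1 was lower in the RV than in the LV in 5 of 5 NF and 4 of 5 LV-HF hearts and higher in 4 of 5 BiV-HF hearts. Two-sided sign flips of the log2 difference within hearts, chosen after seeing the data, gave means of -0.30 ± 0.17 (SD, permutation p = 0.0625, adjusted p = 0.188) in NF, -0.16 ± 0.42 (permutation p = 0.562, adjusted p = 0.562) in LV-HF and 0.33 ± 0.20 (permutation p = 0.125, adjusted p = 0.188) in BiV-HF. With 5 hearts such flips cannot give a p under 0.0625. The differences within hearts were also compared between heart states by exact two-sided permutation of hearts, a test chosen after seeing the data. BiV-HF lay above NF by 0.63 (exact p = 0.00794, the smallest possible) and above LV-HF by 0.48 (exact p = 0.0159), each with adjusted p = 0.0952 over these 3 and the 9 comparisons of levels and adjusted p = 0.0238 over these 3 alone. Over the 3 and the 9 together, too, a difference at the smallest p possible could not have passed alone. LV-HF against NF gave 0.14 (exact p = 0.508, adjusted p = 0.677 and 0.508), and 0.0238 over the 3 without LV-HF heart 5. Whether these differences pass therefore depends on the tests adjusted for, and over the 3 alone the adjusted p of BiV-HF against LV-HF was 0.0714 without BiV-HF heart 1, 3, 4 or 5, 0.0595 without LV-HF heart 1 or 2 and 0.0556 without LV-HF heart 5. Without BiV-HF RV library 2, however, the adjusted p was 0.0357 both for BiV-HF against LV-HF in the RV and for RV against LV in BiV-HF hearts, within ranges of 0.0357 to 0.357 and 0.0357 to 0.375 over all alternatives. The genome-wide edgeR test gave 0.44 (SE 0.17, adjusted p = 0.103) for BiV-HF against NF in the RV and 0.43 (SE 0.16, adjusted p = 0.363) against LV-HF. It gave 0.01 (SE 0.17, adjusted p = 0.979) for LV-HF against NF in the RV, and in the LV -0.10 (SE 0.16, adjusted p = 0.794) for LV-HF against NF, -0.20 (SE 0.15, adjusted p = 0.462) for BiV-HF against NF and -0.09 (SE 0.16, adjusted p = 0.892) for BiV-HF against LV-HF. The change between LV-HF and BiV-HF differed between RV and LV by 0.52 (SE 0.23, adjusted p = 1) without the pairs and had an adjusted p of 0.472 over all genes with the heart as a block, so it did not pass the threshold.

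**Figure D1:**
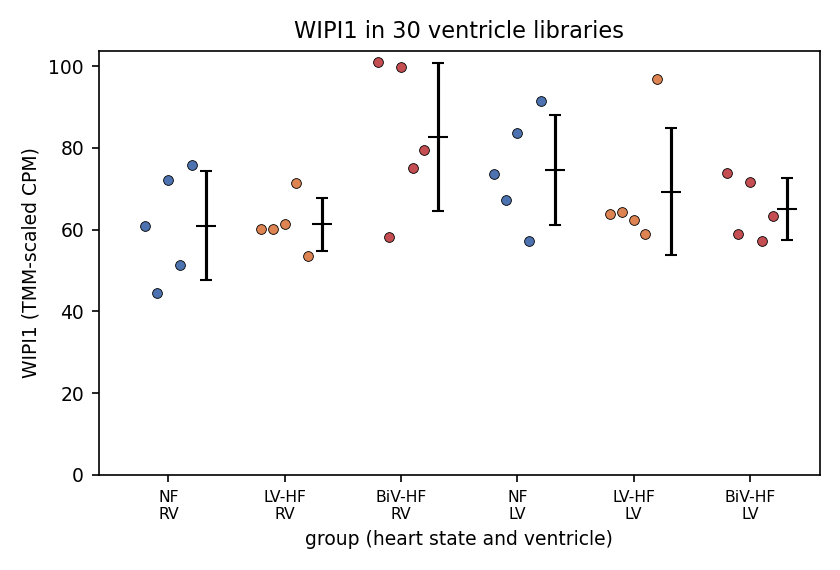
WIPI1 in each of the 30 libraries (points, TMM-scaled CPM on the vertical axis) by heart state and ventricle, with group means and SD as bars beside the points. The BiV-HF RV group has the highest mean, 82.7 ± 18.0 CPM, and its points overlap those of the other groups.

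The failing RV was first compared with the non-failing RV (BiV-HF against NF). NPPB and NPPA, which encode the natriuretic peptides that cardiomyocytes release under wall stress, rose from 8.63 ± 8.06 to 611 ± 642 CPM and from 30.2 ± 30.7 to 1755 ± 2130 CPM (log2 fold changes 6.16 ± 1.09, adjusted p = 0.00442, and 5.86 ± 1.17, adjusted p = 0.00745). MYH6, the fast alpha-myosin heavy chain, fell from 5446 ± 4714 to 256 ± 69.2 CPM (-4.41 ± 1.04, adjusted p = 0.016), although 1 NF RV library had 115 CPM, below the 180 to 359 CPM of the BiV-HF RV libraries. Its adjusted p was 0.0681 with the replicate block and 0.155 by limma on log2 FPKM. Other large rises were those of PENK (the enkephalin precursor, 5.45 ± 0.93), SFRP4 (a secreted Wnt modulator, 5.42 ± 0.82), MXRA5 (4.60 ± 0.50), COMP (a matrix glycoprotein, 4.33 ± 1.20) and FCN1 (a ficolin of monocytes, 4.31 ± 0.79). Other large falls were those of CPLX3 (a complexin, -4.11 ± 0.96), CA14 (a membrane carbonic anhydrase, -3.80 ± 0.55), FGFBP2 (-3.45 ± 0.68), the locus shared by CMTM5 and IL25, LGR6 (an R-spondin receptor, -3.29 ± 0.49) and the lipocalin LCN10 (-3.02 ± 0.45). Of 13279 genes tested, 1362 passed the threshold, 706 higher and 656 lower in BiV-HF. The call of COMP was lost when any 1 of 6 libraries was left out, and that of the CMTM5 and IL25 locus with any 1 of 8. The count was 801 in a fit of the 10 libraries alone, 669 without NF RV libraries 3 and 4 (the richest in MALAT1 and NEAT1) and 209 by limma on log2 FPKM. It was 835 without BiV-HF RV library 2 and 872 without BiV-HF RV library 3.

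Among the gene lists, matrix and inflammatory groups stood higher in the BiV-HF RV and groups of fuel oxidation lower. Of 53 collagen and matrix genes, 31 rose and 1 (TIMP3) fell, against 41 and 1 adjusted over the list alone (median log2 fold change 1.39, adjusted p = 2.04e-23, and adjusted p = 0.145 with an estimated correlation). They included the small leucine-rich proteoglycans LUM (2.78 ± 0.41) and OGN (2.71 ± 0.42) and COL14A1 (2.75 ± 0.42). Fibroblast markers rose with them in 5 of 14, or 5 adjusted over the list alone (median 1.00, adjusted p = 0.000493, and adjusted p = 0.41 with an estimated correlation). In this and the other comparisons a larger share of fibroblasts was not separated from a change within the cells. Myofibroblast markers rose in 6 of 10, or 7 adjusted over the list alone, with THBS4 at 2.38, CTHRC1 at 3.48 and FAP at 2.65 (list adjusted p = 2.07e-07, and adjusted p = 0.145 with an estimated correlation). Neutrophil markers rose in 9 of 12, also 9 adjusted over the list alone (median 3.07, adjusted p = 2.42e-11, and adjusted p = 0.145 with an estimated correlation). Among them was the neutrophil IgG receptor FCGR3B (5.15), whose fragments are hard to part from those of FCGR3A. T and NK cell markers rose in 7 of 8, or 8 adjusted over the list alone (median 3.07, adjusted p = 7.58e-09, and adjusted p = 0.145 with an estimated correlation), among them perforin, PRF1 (3.82), and the chemokine CCL5 (2.97). The table has 16 loci of this list, and those beyond the 8 did not pass the filter on low counts. Interferon-stimulated genes rose in 11 of 33, or 15 adjusted over the list alone (adjusted p = 1.76e-11, and adjusted p = 0.147 with an estimated correlation), with OAS2 at 1.28 and MX2 at 1.38. Antigen-presentation genes rose in 7 of 23, or 14 adjusted over the list alone (adjusted p = 3.23e-08, and adjusted p = 0.318 with an estimated correlation), with CD74 at 1.78.

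Fatty acid oxidation genes fell in 11 of 35 and rose in 0, with 17 lower adjusted over the list alone (median -0.40, adjusted p = 1.43e-08, and adjusted p = 0.145 with an estimated correlation). Both subunits of the mitochondrial trifunctional protein, HADHA (-0.82 ± 0.16) and HADHB (-1.04 ± 0.15), and the acyl-CoA synthetase ACSL1 (-0.68 ± 0.14) were among them. Nuclear genes of oxidative phosphorylation fell in 11 of 79, or 12 adjusted over the list alone, with a median of -0.21 (adjusted p = 1.99e-07, and adjusted p = 0.475 with an estimated correlation). In the autophagy list, to which WIPI1 belongs, 2 of 49 genes fell and 0 rose, the same numbers adjusted over the list alone (adjusted p = 0.0153, and adjusted p = 0.29 with an estimated correlation). The genes that fell were the cargo receptor CALCOCO2 (-0.82 ± 0.13) and WDR45 (-0.86 ± 0.16), a relative of WIPI1. The genes ACE, whose enzyme makes angiotensin II, and MME, or neprilysin, which degrades natriuretic peptides, rose, ACE from 4.83 ± 2.05 to 44.1 ± 27.0 CPM (3.21 ± 0.38) and MME by 2.47 ± 0.28. Both belong to the adrenergic and renin-angiotensin list, of which 5 of 32 rose, or 6 adjusted over the list alone (adjusted p = 0.0223, and adjusted p = 0.145 with an estimated correlation). Erythroid markers rose in 3 of 6, all globins, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0344, and adjusted p = 0.271 with an estimated correlation), among them HBB (3.27 ± 0.80). The table has 12 loci of that list, of which the 6 passed the filter on low counts. Of 42 lists tested in this comparison 23 were called with the preset correlation and 0 with an estimated correlation.

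The RV of hearts failing mainly on the left was compared with the NF RV to ask what changes in an RV next to a failing LV. Immediate-early transcription factors and red- and white-cell genes had large rises: EGR2 (5.24 ± 0.92, adjusted p = 0.00513), FOSB (4.90 ± 0.91), the globins HBA2 (4.85 ± 0.82) and HBB (3.75 ± 0.81). With them rose the protease MMP9 (4.19 ± 0.67), EGR3 (3.84 ± 0.80) and FNDC1 (3.78 ± 0.62). IL1RL1, the interleukin receptor also known as ST2, fell from 20.3 ± 13.1 to 1.08 ± 1.08 CPM (-4.26 ± 0.79, adjusted p = 0.007), and SERPINA3, an acute-phase protease inhibitor, from 139 ± 41 to 13.2 ± 6.97 CPM (-3.38 ± 0.64, adjusted p = 0.0077). The other largest falls were LCN10 (-3.61 ± 0.46), LAD1 (-3.42 ± 0.63), the delta-catenin CTNND2 (-2.94 ± 0.44), PNMT, which turns noradrenaline into adrenaline (-2.58 ± 0.26), the tubulin TUBA3D (-2.52 ± 0.60) and the transsulfuration enzyme CBS (-2.50 ± 0.42). NPPA and NPPB, named here after their values were seen, stood at 23.9 ± 28.8 and 5.61 ± 3.55 CPM, without a call (-0.34 ± 0.98, adjusted p = 0.88, and -0.57 ± 0.99, adjusted p = 0.781). In all 971 genes passed, 525 higher and 446 lower in LV-HF. DESeq2 called 1525, limma on log2 FPKM 122, and edgeR 320 without NF RV libraries 3 and 4, those with the most MALAT1 and NEAT1. Leaving out 1 library gave 520 (LV-HF RV 2), 552 (LV-HF RV 4), 530 (LV-HF RV 5), 614 (NF RV 1) and 529 (NF RV 3).

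Of 29 immediate-early genes 16 rose and 0 fell in the LV-HF RV, with 21 higher adjusted over the list alone (median 1.45, adjusted p = 1.1e-16, and adjusted p = 0.186 with an estimated correlation). EGR1 went from 58.1 ± 51.4 to 702 ± 284 CPM (3.59 ± 0.58, adjusted p = 0.0039) and the matricellular gene CYR61 by 2.39 ± 0.44. Collagen and matrix genes rose in 16 of 53, or 24 adjusted over the list alone (adjusted p = 9.6e-14, and adjusted p = 0.349 with an estimated correlation), with OGN at 3.22 ± 0.42 and LUM at 2.95 ± 0.42, and so did fibroblast markers in 4 of 14, or 6 adjusted over the list alone (median 0.89, adjusted p = 5.22e-05, and adjusted p = 0.358 with an estimated correlation). Interferon-stimulated genes rose in 9 of 33, or 15 adjusted over the list alone (adjusted p = 1.01e-11, and adjusted p = 0.328 with an estimated correlation), OAS3 by 1.32 ± 0.25. Neutrophil markers rose in 7 of 12, or 9 adjusted over the list alone (adjusted p = 2.56e-07, and adjusted p = 0.339 with an estimated correlation), MNDA by 2.67 ± 0.58. Glucocorticoid-response genes fell in 4 of 19, or 5 adjusted over the list alone, with HIF3A at -1.46 ± 0.29 and KLF15 at -1.75 ± 0.37 (adjusted p = 6.09e-05, and adjusted p = 0.358 with an estimated correlation). In the autophagy list 5 of 49 genes fell, or 6 adjusted over the list alone (adjusted p = 0.0031, and adjusted p = 0.339 with an estimated correlation). BECN1, the beclin of the class III lipid kinase complex (-0.48 ± 0.10), and CALCOCO2 (-0.70 ± 0.13) were among them. ACE rose here too, to 57.4 ± 12.7 CPM (3.59 ± 0.38, adjusted p = 0.000313). Adipocyte markers stood higher by a median of 1.23 (adjusted p = 0.0432, and adjusted p = 0.626 with an estimated correlation), with 0 of 15 members higher and 1 lower, the same adjusted over the list alone.

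**Figure D2:**
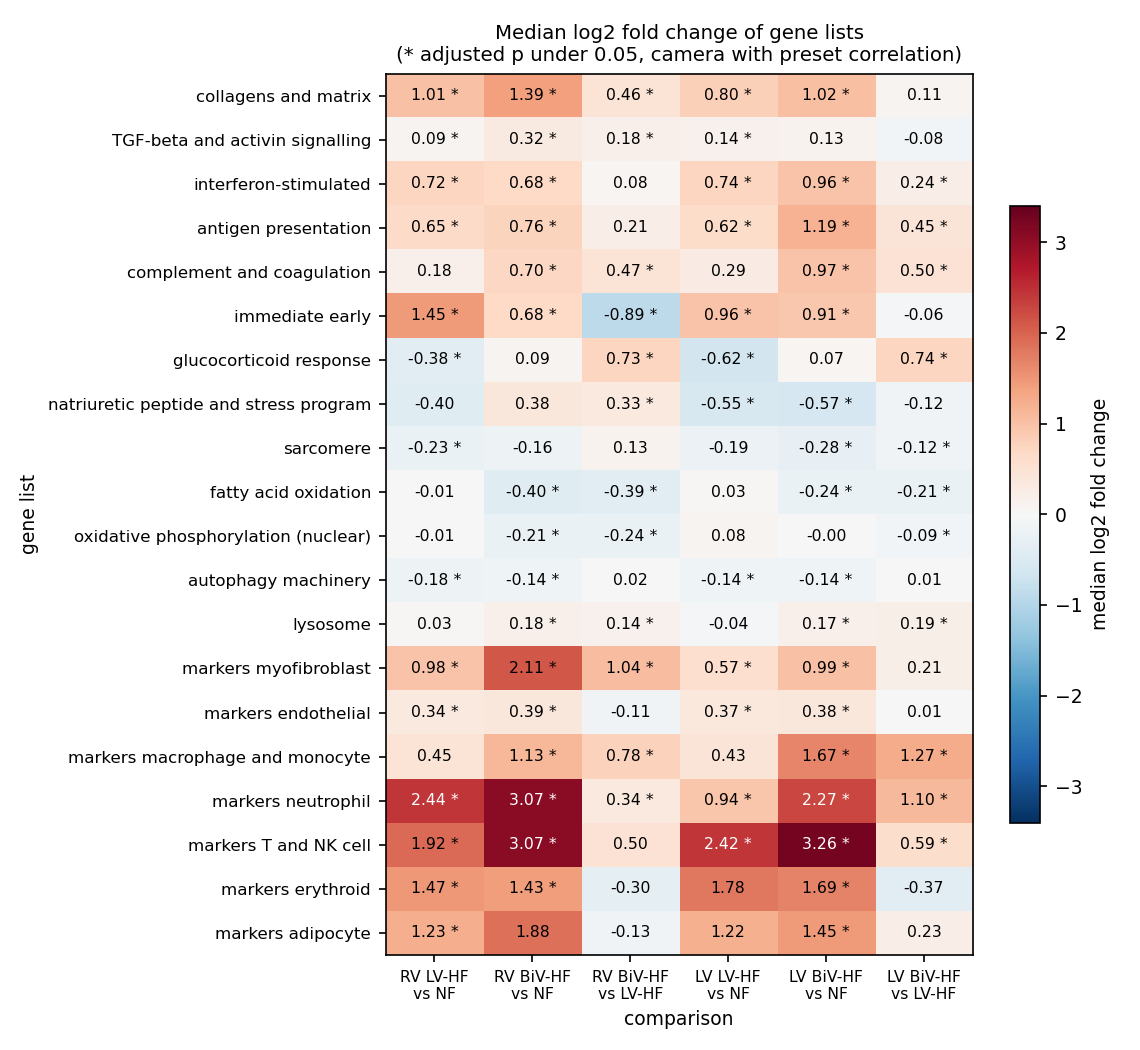
Median log2 fold change of 20 gene lists (vertical axis) in the 6 comparisons of heart states within a ventricle (horizontal axis), with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Collagens and matrix, T and NK cell and interferon-stimulated genes have positive medians in both ventricles of LV-HF and BiV-HF hearts against NF.

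Genes called in both RV comparisons, among them ACE, LUM and LCN10, moved in a common direction with 1 exception. Both comparisons share the NF libraries, so overlap was measured against simulations. Higher in both were 315 genes and lower in both 242, with 1 called in opposite directions, where independent lists of those sizes would share 27.9 and 22.03. The covariance of the fold changes over genes was 0.288 against 0.046 in simulations without effects that kept the shared controls (r over genes 0.769 against 0.511, genes not being independent replicates). With the NF libraries split between the comparisons, a mean of 36.5 genes were higher and 32.1 lower in both, where independent lists would share 2.6 and 4.0. These fits have fewer NF libraries per comparison and called fewer genes, a mean of 585.65 for BiV-HF and 390.9 for LV-HF. Their counts are therefore not on the scale of the 315 and 242. The mean covariance was 0.235. In the LV the same counts were 185 and 116, with 0 in opposite directions and independent lists sharing 12.8 and 7.18, and the covariance was 0.245 against 0.051 (r 0.734 against 0.497). With the NF libraries split there, a mean of 27.6 genes were higher and 22.1 lower in both, where independent lists would share 1.6 and 2.2. Mean calls were 470.55 for BiV-HF and 246.5 for LV-HF, and the mean covariance was 0.184. Across all 4 comparisons with NF, 149 genes were called, 104 higher in each, 45 lower in each and 0 mixed. These comparisons share NF libraries within a ventricle and hearts across ventricles, and no value without effects was computed for the 149. Named after their values were seen, they include ACE, MME, OGN, LUM, PRF1 and the apelin receptor APLNR on the higher side. LAD1, LCN10, FCN3, MYOT, HIF3A and CALCOCO2 are on the lower side.

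The comparison of BiV-HF with LV-HF in the RV asks what sets the failing RV apart from an RV beside a failing LV. NPPB rose by 6.73 ± 1.11, and PDE8B, a phosphodiesterase for cyclic AMP, and CTNND2 by 2.99 ± 0.50 and 2.75 ± 0.44. ABRA, an actin-binding protein of striated muscle, fell from 123 ± 36.6 to 25.5 ± 11.9 CPM (-2.28 ± 0.33). ADAM11 (-2.54 ± 0.40), FEZ1 (-0.84 ± 0.14) and C11orf67 (-0.80 ± 0.13) fell as well. CTNND2 stood at 25.8 ± 14.6 CPM in NF, 3.44 ± 2.09 in LV-HF and 22.8 ± 8.09 in BiV-HF, and PDE8B at 4.03 ± 2.4, 1.85 ± 0.781 and 14.8 ± 6.29. NPPA had 6.20 (SE 1.19, adjusted p = 0.0557) and did not pass. Of 13279 genes edgeR called 8, 3 higher and 5 lower, each at adjusted p = 0.0359, and 1447 had an unadjusted p under 0.05. DESeq2 called 172, edgeR with upper-quartile scaling 25 (6 higher and 19 lower), the 10 libraries alone 36, a fit of all 30 libraries 0 and limma on log2 FPKM 1. Without 1 library the count was 2 (BiV-HF RV 1), 0 (BiV-HF RV 2), 0 (BiV-HF RV 3), 20 (BiV-HF RV 4), 1 (LV-HF RV 1), 0 (LV-HF RV 2), 2 (LV-HF RV 3), 19 (LV-HF RV 4) and 0 (LV-HF RV 5). Each of the 8 calls was thus lost with some library.

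**Figure D3:**
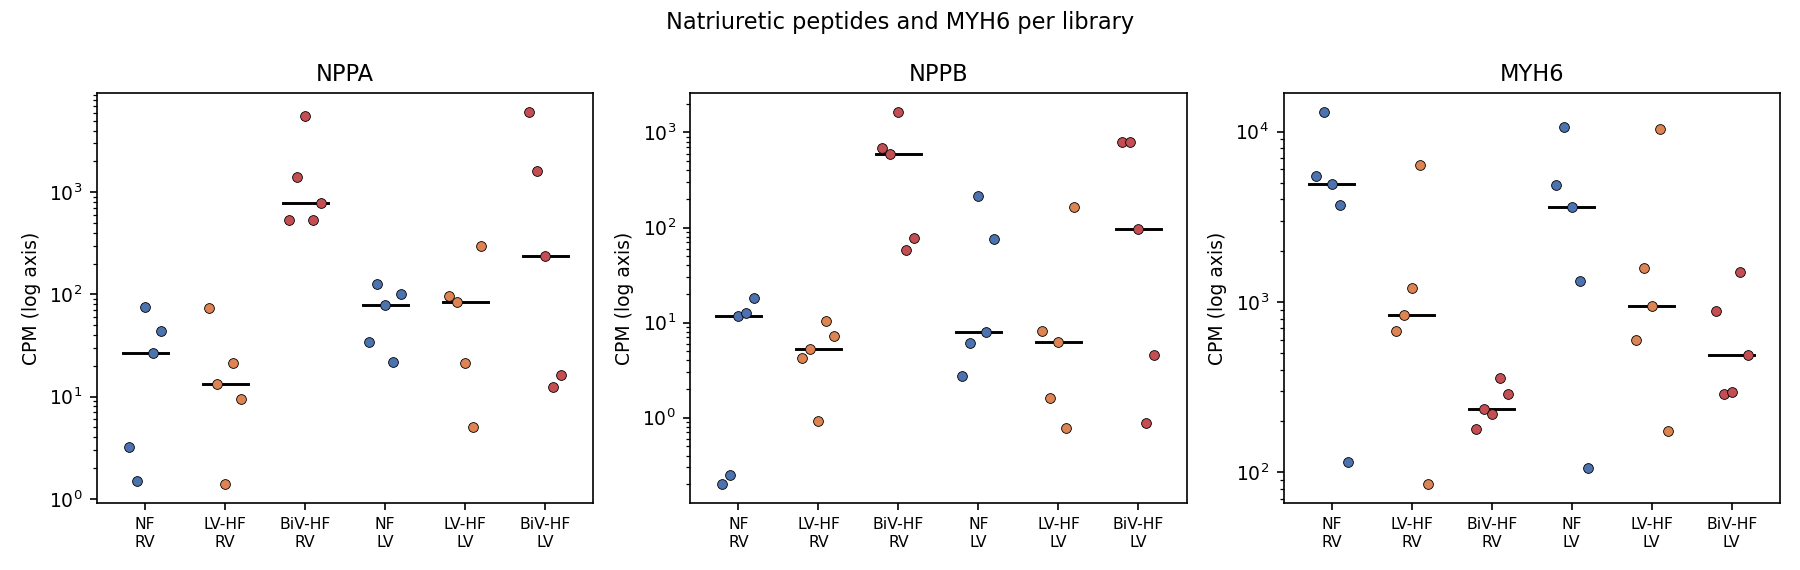
NPPA, NPPB and MYH6 in each library (points, CPM on a log axis) by heart state and ventricle, with the group median as a line. NPPA lies at 529 CPM or more in each BiV-HF RV library and at or under 75.2 CPM in each NF RV library. For MYH6, 1 NF RV library lies at 115 CPM, under all BiV-HF RV libraries.

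Fatty acid oxidation genes stood lower in BiV-HF RV than in LV-HF RV with a median of -0.39, with 0 of 35 called over all genes and 19 lower adjusted over the list alone (adjusted p = 2.83e-14, and adjusted p = 0.128 with an estimated correlation). HADHB (-0.76 ± 0.15, adjusted p = 0.0567) and the mitochondrial carrier UCP3 (-2.96 ± 0.59, adjusted p = 0.0574) had the smallest p. For oxidative phosphorylation 0 of 79 were called and 2 were lower adjusted over the list alone (median -0.24, adjusted p = 1.85e-13, and adjusted p = 0.607 with an estimated correlation). Immediate-early genes were lower with a median of -0.89, with 0 of 29 called and 7 lower adjusted over the list alone (adjusted p = 6.29e-08, and adjusted p = 0.47 with an estimated correlation). Glucocorticoid-response genes were higher by a median of 0.73, with 0 of 19 called and 8 higher adjusted over the list alone (adjusted p = 1.19e-09, and adjusted p = 0.47 with an estimated correlation). Myofibroblast markers had 0 of 10 called and 5 higher adjusted over the list alone (adjusted p = 0.000687, and adjusted p = 0.511 with an estimated correlation), with POSTN at 2.71 (SE 0.78, adjusted p = 0.221). In the natriuretic and stress list 1 of 17 rose (NPPB), or 2 adjusted over the list alone (adjusted p = 0.000762, and adjusted p = 0.47 with an estimated correlation). Macrophage and monocyte markers stood higher by a median of 0.78 with 0 of 17 called either way or adjusted over the list alone (adjusted p = 0.0275, and adjusted p = 0.907 with an estimated correlation).

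In the LV, left-sided failure was compared with NF to describe the chamber that fails in those hearts. The growth factor PTN (2.83 ± 0.26, adjusted p = 0.000133), ACE (3.18 ± 0.38, adjusted p = 0.000787, from 5.62 ± 3.61 to 51.1 ± 11.8 CPM), the apelin receptor APLNR (3.70 ± 0.55, adjusted p = 0.00334) and OGN (3.30 ± 0.44, adjusted p = 0.00172) rose. HBB (3.78 ± 1.00), CHRDL1, a BMP antagonist (3.25 ± 0.70), EGR1 (3.06 ± 0.79) and FNDC1 (3.01 ± 0.69) complete the largest rises. LAD1 (-3.81 ± 0.62), LCN10 (-3.42 ± 0.55), FCN3, a lectin-pathway ficolin (-2.63 ± 0.42), and MYOT, the Z-disc protein myotilin (-2.71 ± 0.50), fell. The other largest falls were IL1RL1 (-3.45 ± 0.82), SERPINA3 (-3.06 ± 0.76), TUBA3D (-2.79 ± 0.61) and GALNTL2 (-2.32 ± 0.46). Of 13360 genes 484 passed, 287 higher and 197 lower, and with upper-quartile scaling 463, of which 330 were higher and 133 lower. DESeq2 called 951, the 10 libraries alone 317 and limma on log2 FPKM 35. The count was 306 without LV-HF LV library 2, 248 without LV-HF LV 3 and 312 without LV-HF LV 4. Calls were lost when any 1 of 7 libraries was left out for HBB, EGR1 and SERPINA3, 1 of 6 for IL1RL1 and FNDC1 and 1 of 2 for CHRDL1, and TUBA3D lost its call without LV-HF LV library 3.

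Collagen and matrix genes rose in 9 of 53 in the LV-HF LV, or 20 adjusted over the list alone (median 0.80, adjusted p = 1.97e-15, and adjusted p = 0.374 with an estimated correlation), with FRZB at 2.12 ± 0.37 and TIMP2 at 1.20 ± 0.20. Fibroblast markers rose as well in 3 of 14, or 5 adjusted over the list alone (median 0.85, adjusted p = 2.38e-07, and adjusted p = 0.284 with an estimated correlation). Interferon-stimulated genes rose in 10 of 33, or 19 adjusted over the list alone (adjusted p = 2.8e-14, and adjusted p = 0.232 with an estimated correlation), BST2 by 1.01 ± 0.20. T and NK cell markers rose in 4 of 9, or 6 adjusted over the list alone (adjusted p = 3.73e-08, and adjusted p = 0.133 with an estimated correlation), the granule protein gene NKG7 by 3.66 ± 0.63. In the natriuretic and stress list 2 of 17 genes fell, the same adjusted over the list alone, with a median of -0.55 (adjusted p = 0.0132, and adjusted p = 0.43 with an estimated correlation). Those were MYOT and the intermediate filament gene DES (-0.70 ± 0.15), both structural genes, and NPPA, named after its values were seen, had 0.49 (SE 1.26, adjusted p = 0.885). Glucocorticoid-response genes fell in 3 of 19, or 5 adjusted over the list alone (adjusted p = 1.76e-05, and adjusted p = 0.43 with an estimated correlation), HIF3A among them (-1.42 ± 0.28).

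BiV-HF was compared with NF in the LV as well. HLA-DRB5, an HLA class II beta chain in a region of near-identical copies (4.23 ± 0.84), MMP9 (3.98 ± 0.74), the chemokine CXCL14 (3.87 ± 0.84) and IL2RG, the common gamma chain of cytokine receptors (3.54 ± 0.68), rose. ACSL6 (6.03 ± 1.57, adjusted p = 0.0323), CCL18 (5.05 ± 1.35), the stearoyl-CoA desaturase SCD (3.76 ± 1.02) and SLAMF8 (3.50 ± 0.93) were also among the 8 largest rises. ACSL6, a brain acyl-CoA synthetase, rested on BiV-HF LV library 3, with 1432 CPM against 4.05 to 9.25 CPM in the other BiV-HF LV libraries. LAD1 (-3.20 ± 0.59), MYOT (-2.60 ± 0.49), FCN3 (-2.07 ± 0.40) and LCN10 (-2.24 ± 0.50) fell, as did GSG2 (-2.71 ± 0.67), the muscle stress gene ANKRD2 (-2.40 ± 0.55), calponin, CNN1 (-2.33 ± 0.68), and filamin C, FLNC (-1.91 ± 0.46). In all 1083 genes passed, 596 higher and 487 lower, against 695 higher and 306 lower with upper-quartile scaling. DESeq2 called 1773, the 10 libraries alone 404 and limma on log2 FPKM 68. The count was 416 without BiV-HF LV library 1, 570 without BiV-HF LV 2, 571 without NF LV 2 and 601 without NF LV 4. Calls were lost with 1 of 5 libraries left out for ACSL6, CCL18 and SLAMF8, 1 of 6 for SCD, 1 of 4 for GSG2 and 1 of 7 for CNN1, and without BiV-HF LV library 1 for ANKRD2 and FLNC.

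Interferon-stimulated genes rose in 18 of 33 in the BiV-HF LV, or 24 adjusted over the list alone (median 0.96, adjusted p = 5.68e-19, and adjusted p = 0.0963 with an estimated correlation), with IFI6 at 1.52 ± 0.20. Antigen-presentation genes rose in 16 of 23, or 19 adjusted over the list alone (adjusted p = 6.55e-15, and adjusted p = 0.283 with an estimated correlation), HLA-DMA by 1.96 ± 0.35. T and NK cell markers rose in 8 of 9, the same adjusted over the list alone (adjusted p = 8.29e-13, and adjusted p = 0.0555 with an estimated correlation), CD3E, a T cell receptor chain, by 4.00 ± 0.73. Macrophage and monocyte markers rose in 3 of 17, or 13 adjusted over the list alone (adjusted p = 5.31e-07, and adjusted p = 0.366 with an estimated correlation), the folate receptor FOLR2 by 2.11 ± 0.40. Collagen and matrix genes rose in 17 of 53, or 22 adjusted over the list alone (adjusted p = 4.47e-15, and adjusted p = 0.283 with an estimated correlation). Sarcomere genes fell in 4 of 23, the same adjusted over the list alone (adjusted p = 0.000184, and adjusted p = 0.283 with an estimated correlation), titin among them. Cardiomyocyte markers fell in 2 and rose in 1 of 11, or 3 and 1 adjusted over the list alone (median -0.26, adjusted p = 0.00722, and adjusted p = 0.366 with an estimated correlation). Fibroblast markers rose in 3 of 14, or 5 adjusted over the list alone (median 1.06, adjusted p = 7.26e-06, and adjusted p = 0.283 with an estimated correlation). Endothelial markers rose in 1 of 14, with 6 higher and 1 lower adjusted over the list alone (median 0.38, adjusted p = 0.00523, and adjusted p = 0.3 with an estimated correlation). A lower share of cardiomyocytes was thus not separated from the fall of sarcomere genes. Calcium-handling and ion channel genes rose in 2 and fell in 9 of 43, or 4 and 14 adjusted over the list alone (adjusted p = 0.00477, and adjusted p = 0.366 with an estimated correlation). Adipocyte markers, read as a sign of fat in the piece, rose in 2 and fell in 1 of 13, or 8 and 1 adjusted over the list alone (adjusted p = 0.0382, and adjusted p = 0.489 with an estimated correlation). NPPA and, named after its values were seen, NPPB had 4.46 (SE 1.44, adjusted p = 0.0683) and 2.48 (SE 1.62, adjusted p = 0.362).

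Between BiV-HF and LV-HF in the LV, macrophage markers, glucocorticoid-response genes and fatty acid oxidation genes differed as lists while no gene passed. Macrophage and monocyte markers stood higher in BiV-HF by a median of 1.27, with 0 of 17 called and 10 higher adjusted over the list alone (adjusted p = 1.43e-09, and adjusted p = 0.435 with an estimated correlation), CD163, the haemoglobin scavenger receptor, having 2.76 (SE 0.77, adjusted p = 0.332). Glucocorticoid-response genes were higher by a median of 0.74, with 0 of 19 called and 4 higher adjusted over the list alone (adjusted p = 1.12e-11, and adjusted p = 0.435 with an estimated correlation), the metallothionein MT2A having 2.08 (SE 0.53, adjusted p = 0.332). Fatty acid oxidation genes were lower with a median of -0.22 with 0 of 35 called, also when adjusted over the list alone (adjusted p = 2.4e-06, and adjusted p = 0.439 with an estimated correlation). The smallest p belonged to KCNAB2 (0.70 ± 0.14), AGT, angiotensinogen (0.65 ± 0.15), and TCFL5 (0.74 ± 0.17) among higher genes. Among lower genes it belonged to C9orf3 (-0.66 ± 0.13), FILIP1 (-0.58 ± 0.12) and NF1 (-0.43 ± 0.09), each of the 6 at adjusted p = 0.332. Of 13360 genes edgeR called 0, with 1389 at an unadjusted p under 0.05, against 66 by DESeq2 and 1 by edgeR without LV-HF LV library 3.

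RV and LV were compared within each heart state, where equal library numbers belong to 1 heart. Over 9597 loci, the residual profile of every RV library was closest to the LV library of its own number (15 of 15, median r 0.619). Natriuretic and stress genes stood lower in the NF RV than in the NF LV with a median of -0.63, with 0 of 17 called, also when adjusted over the list alone (adjusted p = 0.00145, and adjusted p = 0.628 with an estimated correlation). Adipocyte markers stood higher in the RV by medians of 1.78 in NF, 0.99 in LV-HF and 0.65 in BiV-HF, with 0 members called in any state, also when adjusted over the list alone. Their adjusted p were 0.000136, 3.48e-07 and 0.00249. With an estimated correlation these were adjusted p = 0.778, 0.341 and 0.939. Immediate-early genes stood higher in the RV in LV-HF by a median of 0.74, with 0 of 29 called, also when adjusted over the list alone (adjusted p = 4.75e-17, and adjusted p = 0.341 with an estimated correlation). Oxidative phosphorylation genes stood lower in the RV in BiV-HF with a median of -0.16, with 0 of 79 called in either way of adjusting, over all genes or adjusted over the list alone (adjusted p = 6.64e-10, and adjusted p = 0.939 with an estimated correlation). Of 13751 genes edgeR without the pairs called 0 in each state, with 857, 586 and 588 at an unadjusted p under 0.05 in NF, LV-HF and BiV-HF (2185, 1785 and 1652 with the heart as a block), and DESeq2 called 3, 10 and 7. The smallest p belonged in NF to LGR6 (2.05 ± 0.44), FGFBP2 (2.56 ± 0.64), NEGR1 (0.87 ± 0.22), CLEC16A (-0.49 ± 0.12), EDIL3 (-2.96 ± 0.69) and ARHGAP35 (-0.42 ± 0.10).

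With the heart as a block, edgeR called 46 genes in NF hearts, 28 higher and 18 lower in the RV, and 0 in LV-HF and BiV-HF. CPLX3 had the smallest p (3.10 ± 0.40, adjusted p = 0.00782). Others, chosen after their values were seen, were LGR6 (1.97 ± 0.36), NEAT1 (0.94 ± 0.18), the natriuretic peptide clearance receptor NPR3 (-1.60 ± 0.31), protein S, PROS1 (-1.22 ± 0.24), and clusterin, CLU (-0.81 ± 0.16). The mean log2 difference of RV and LV in NF, LV-HF and BiV-HF hearts was 0.929, 0.284 and 0.157 for NEAT1. For MALAT1 it was 0.683, -0.247 and 0.214. Whether the 46 calls depend on a difference in nuclear-retained RNA was not tested. The sarcomere list stood lower in the NF RV with a median of -0.19, and 0 of 23 genes were called, also when adjusted over the list alone. It had adjusted p = 0.0229 without the block, 0.0553 with it and adjusted p = 0.907 with an estimated correlation. Fibroblast markers in LV-HF stood higher in the RV with a median of 0.27, and 0 of 14 were called, also when adjusted over the list alone. They had adjusted p = 0.0365, 0.0934 with the block and adjusted p = 0.687 with an estimated correlation. The smallest p in LV-HF and BiV-HF belonged to SNORD loci, which the naming rule leaves out and which were named after their values were seen. In LV-HF SNORD42A had -4.87 ± 0.88, adjusted p = 0.058 and SNORD55 -3.30 ± 0.62, adjusted p = 0.058. In BiV-HF SNORD42A had -4.99 ± 0.89, adjusted p = 0.0529, SNORD99 -3.72 ± 0.68, adjusted p = 0.0529 and SNORD55 -3.34 ± 0.63, adjusted p = 0.0529. In LV-HF other genes with small p were CSPP1 (-0.67 ± 0.13, adjusted p = 0.058), CTNND2 (-2.36 ± 0.58), YJEFN3 (-0.998 ± 0.246), MANBAL (0.49 ± 0.13) and TRAPPC5 (0.54 ± 0.14). In BiV-HF they were ACSL6 (-5.88 ± 1.19, adjusted p = 0.115, resting on LV library 3), STARD9 (-1.72 ± 0.40), ANXA3 (-0.70 ± 0.17), GSG2 (3.32 ± 0.84), NFAT5 (0.45 ± 0.12) and POM121C (0.47 ± 0.12). There 2 genes were called without BiV-HF LV library 1, 3 without a filter and 3 with a CPM of at least 5.

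**Figure D4:**
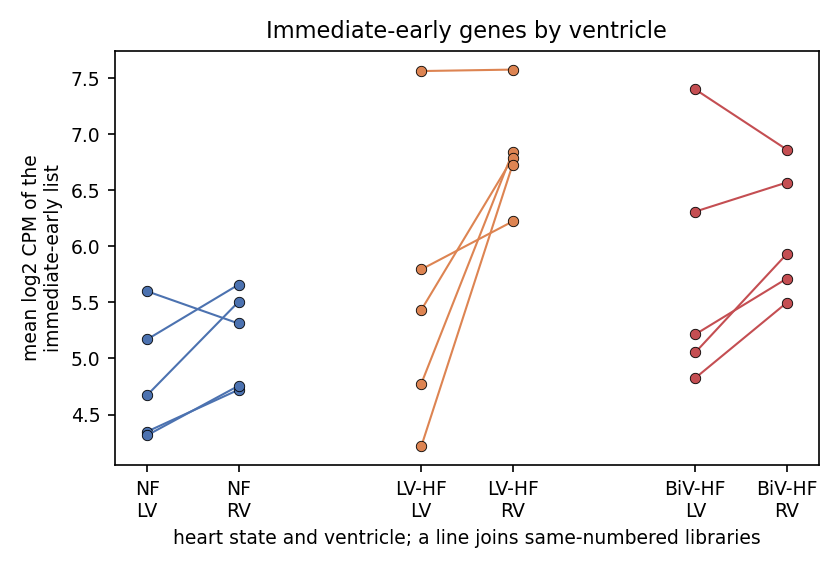
Mean log2 CPM of the immediate-early list in the LV and RV library of each heart (points, joined by a line for each heart) in the 3 heart states. The RV value is above the LV value in 13 of 15 hearts.

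Whether the step from LV-HF to BiV-HF differs between RV and LV was tested as an interaction. Immediate-early genes moved lower in the RV than in the LV with a median of -0.74, with 0 of 29 called, also when adjusted over the list alone (adjusted p = 5.63e-07, and adjusted p = 0.933 with an estimated correlation). Sarcomere and natriuretic and stress genes moved higher in the RV by medians of 0.24 and 0.44, with 0 of 23 and 0 of 17 called, also when adjusted over the list alone. Their adjusted p were 0.000175 and 0.000537, and both had adjusted p = 0.923 with an estimated correlation. Macrophage markers moved lower in the RV with a median of -0.73, with 0 of 18 called, also when adjusted over the list alone (adjusted p = 0.000304, and adjusted p = 0.951 with an estimated correlation). The smallest p belonged to the locus of EMILIN1 and KHK, LAMA2 (0.72 ± 0.21) and SLAIN2 (0.47 ± 0.14) among higher genes and to C9orf142 (-0.87 ± 0.20), SNCG (-1.46 ± 0.38) and ACSL6 (-5.99 ± 1.56, resting on BiV-HF LV library 3) among lower ones. The edgeR interaction test called 0 of 13751 genes, with 335 at an unadjusted p under 0.05 (1187 with the heart as a block), and DESeq2 called 0. For the step from NF to LV-HF the interaction test of edgeR called 0 genes, with 210 at an unadjusted p under 0.05 (798 with the heart as a block), DESeq2 1, and edgeR 1 without NF LV library 5. There neutrophil markers moved higher in the RV than in the LV by a median of 1.53, with 0 of 12 called, also when adjusted over the list alone (adjusted p = 2.4e-06, and adjusted p = 0.955 with an estimated correlation), and WIPI1 had 0.11 (SE 0.23, adjusted p = 1). The smallest p there belonged to C7orf60 (0.52 ± 0.16), TRAPPC5 (0.56 ± 0.20), ZNF687 (0.44 ± 0.15), CSPP1 (-0.82 ± 0.18), SHISA9 (-0.84 ± 0.23) and C11orf48 (-0.71 ± 0.22).

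WIPI1 was lastly set against the gene lists over the 15 libraries of each ventricle, with group means removed. Of 88 relations 0 passed after adjustment (1 without LV-HF RV library 1) and 9 had an unadjusted p under 0.05. The autophagy list in the RV had Pearson r 0.544 (permutation p = 0.0371, adjusted p = 0.375) and Spearman rho 0.543 (permutation p = 0.0386), with r 0.509 without the 2 libraries farthest from the median of WIPI1. Without removing the group means its r in the RV was 0.055 (permutation p = 0.845). The same list in the LV had r 0.108 (permutation p = 0.704, adjusted p = 0.861), with r -0.216 without the 2. In the LV the natriuretic and stress list had r 0.723 (two-sided permutation p = 0.00229, adjusted p = 0.0678) and Spearman rho 0.625 (permutation p = 0.0147), with r 0.58 without the 2. Schwann and neuronal markers in the RV had r -0.725 (permutation p = 0.00231, adjusted p = 0.0678) and rho -0.779 (permutation p = 0.00105), with r -0.634 without the 2. Lymphatic endothelial markers in the RV had r -0.741 (permutation p = 0.00197, adjusted p = 0.0678) and rho -0.711 (permutation p = 0.00407), with r -0.474 without the 2. Without removing the group means 1 relation passed, that of Schwann and neuronal markers in the RV (r -0.784, permutation adjusted p = 0.0405).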

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

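The whole-heart test of the immediate-early genes, both tests of blood-cell markers and the genes searched for distant libraries were chosen only after the result was seen, and the depth, adipose and nuclear-RNA tests before, although the NF libraries left out in the last were picked from the data. In 28 of 102 groups of 5 libraries, 1 library lay far from the others, its gap to the nearest being over 0.71 of the range of the group. Chance gives about 1 in 20 for normally spread values. The genes were picked after their values were seen and CPM are skewed, so the count of 28 is no test of an uneven spread, and no explanation was tested for the single values that follow.

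For WIPI1, LV-HF LV library 5 had 96.9 CPM (others 59 to 64.4). For NPPA, LV-HF RV library 1 had 73.9 CPM (others 1.39 to 21.5), BiV-HF RV library 3 had 5511 CPM (others 529 to 1410) and BiV-HF LV library 1 had 6083 CPM (others 12.5 to 1596). For NPPB, LV-HF LV library 5 had 163 CPM (others 0.772 to 8.25). For MYH6, LV-HF RV library 4 had 6372 CPM (others 85.3 to 1205) and LV-HF LV library 4 had 10365 CPM (others 174 to 1587). For SFRP4, NF RV library 3 had 1.88 CPM (others 0.166 to 0.599) and BiV-HF LV library 1 had 70.7 CPM (others 3.24 to 17.7). For FOSB, LV-HF RV library 3 had 718 CPM (others 60.1 to 220), BiV-HF RV library 5 had 258 CPM (others 15.7 to 63.1), LV-HF LV library 3 had 397 CPM (others 0.515 to 16.2) and BiV-HF LV library 5 had 334 CPM (others 1.5 to 6.45). For EGR1, LV-HF RV library 4 had 197 CPM (others 800 to 865) and BiV-HF RV library 5 had 474 CPM (others 160 to 210). For HBB, NF RV library 3 had 26.8 CPM (others 0.399 to 7.93) and BiV-HF RV library 4 had 251 CPM (others 18.1 to 59.3). For IL1RL1, LV-HF RV library 3 had 2.93 CPM (others 0.145 to 0.936) and BiV-HF LV library 5 had 26.8 CPM (others 0.76 to 6.1). For CCL18, NF RV library 4 had 7.45 CPM (others 0 to 1.1), LV-HF RV library 5 had 32.5 CPM (others 1.02 to 9.26), NF LV library 4 had 3.76 CPM (others 0.123 to 0.398) and LV-HF LV library 4 had 8.88 CPM (others 0.162 to 1.47). For ACSL6, BiV-HF LV library 3 had 1432 CPM (others 4.05 to 9.25). For PDE8B, BiV-HF RV library 1 had 3.72 CPM (others 16.1 to 18.9) and NF LV library 3 had 33.4 CPM (others 7.52 to 14.5). For ABRA, LV-HF LV library 3 had 496 CPM (others 11.8 to 115) and BiV-HF LV library 5 had 116 CPM (others 15 to 19.4).

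By a test of the difference itself, camera called the gene lists that follow between the RV and LV responses at the preset correlation only, and with an estimated correlation each had an adjusted p of 0.48 or more. They are given as median log2 difference with the adjusted p at the preset correlation. From LV-HF to BiV-HF the RV moved lower than the LV in immediate-early genes (-0.74, adjusted p = 5.63e-07), macrophage and monocyte markers (-0.73, 0.000304), oxidative phosphorylation (-0.13, 0.000679), antigen presentation (-0.35, 0.000893), NADPH oxidases and antioxidants (-0.23, 0.000893), cytokines (-0.36, 0.0125), T and NK cell markers (-0.40, 0.0137), neutrophil markers (-0.78, 0.0153) and interferon-stimulated genes (-0.23, 0.0181), each lost with an estimated correlation. It moved higher in sarcomere (0.24, 0.000175), natriuretic and stress (0.44, 0.000537), TGF-beta (0.25, 0.00206), myofibroblast (0.71, 0.0109), collagen and matrix (0.31, 0.0137), cardiomyocyte (0.20, 0.0241, and 0.0594 with the heart as a block) and heat shock genes (0.11, 0.0341), again each lost with that setting. From NF to LV-HF the RV moved higher in neutrophil markers (1.53, 2.4e-06) and immediate-early genes (0.43, 2.4e-06) and lower in oxidative phosphorylation (-0.088, 0.000719), also lost with it. In the interactions edgeR called 0 genes, with 335 (BiV-HF and LV-HF) and 210 (LV-HF and NF) at an unadjusted p under 0.05, and DESeq2 called 0 and 1.

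Immediate-early genes stood higher in the RV than in the LV of a heart in 13 of 15 hearts, by a mean of 0.666 (SD 0.807, two-sided sign-flip permutation p = 0.00293). The mean was 1.275 in LV-HF hearts (permutation p = 0.0625), 0.37 in NF hearts (permutation p = 0.125) and 0.354 in BiV-HF hearts (permutation p = 0.25), where 5 hearts cannot give a p under 0.0625. Handling of the whole heart cannot be told apart, since its test restates this difference and could not have come out otherwise. Unequal depth as the whole cause is argued against, since the difference at equal depth was 0.682 (SE 0.221). More adipose tissue in the RV piece cannot be told apart: at equal adipocyte markers the difference was 0.317 (SE 0.265). A difference in RNA or library making between RV and LV pieces stays open and was not tested, and the sum of SNORD loci, higher in the RV in 1 of 15 hearts, differs by ventricle too. A biological difference between the ventricles remains open and untested.

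By camera at the preset correlation, erythroid and neutrophil markers stood higher than in NF in the RV of BiV-HF (adjusted p = 0.0344 and 2.42e-11, and 0.271 and 0.145 with an estimated correlation) and LV-HF hearts (0.0322 and 2.56e-07, and 0.339 for both with it). In the LV they did in BiV-HF hearts (0.0299 and 1.69e-09, and 0.275 for both with it). In LV-HF hearts neutrophil markers did (0.0132, and 0.577 with it) and erythroid markers did not pass (0.106, and 0.374 with it). A lower share of cardiomyocytes would raise the markers of other cells alike, yet the neutrophil score rose more than the endothelial score in the RV of BiV-HF hearts, by 2.232 (SE 0.345, exact p = 0.00794). Blood left in the piece cannot be told apart from cells in the tissue: the 2 scores had r 0.472 in the RV (permutation p = 0.0766, adjusted p = 0.153, rho 0.325, permutation p = 0.236, r 0.492 without the 2 farthest) and r 0.343 in the LV (permutation p = 0.209, adjusted p = 0.209, rho 0.032, permutation p = 0.913, r 0.063 without the 2 farthest), over 2 relations. A response of the failing heart itself stays open as well.

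NF RV libraries 3 and 4 were the richest in nuclear-retained RNA, and leaving them out gave 669 calls for BiV-HF against NF in the RV. The other 9 of 10 pairs of NF libraries gave 475 to 1539 with a median of 809, so that pair alone does not set the count. Values looked at afterwards leave a wider dependence open: over the 10 pairs the count had a rank correlation with the MALAT1 and NEAT1 level of the NF libraries kept of 0.467 for BiV-HF and 0.733 for LV-HF, where counts ran from 156 to 1275 with 320 without libraries 3 and 4. The pairs share libraries, so these correlations carry no p. Heart state as the source of the calls is the design's own explanation and was not tested apart from it.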

How the results depend on the processing

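Limma on FPKM, the fits without NF RV libraries 3 and 4, the WIPI1 level on FPKM and the WIPI1 tests within hearts were chosen after seeing the data. No result past its threshold changed direction under the alternatives run. Differences without a call did: the WIPI1 log2 ratio of LV-HF to NF in the RV went from 0.009 to -0.085, -0.046 and -0.051 without NF RV 2, NF RV 4 and LV-HF RV 4, and that of BiV-HF to LV-HF in the LV from -0.092 to 0.059 without LV-HF LV 5. Of the single genes 13499 values kept their side of the threshold, 207 newly passed and 1031 no longer passed, and of the lists 538, 31 and 312. Direction was checked only for results that had passed the threshold, so values without a call may have changed direction. The cause of the changes was not tested. Fits with fewer libraries gave fewer calls in some cases and more in others.

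DESeq2 called 1525 genes in the RV for LV-HF against NF (edgeR 971), 172 for BiV-HF against LV-HF (8), and in the LV 951 for LV-HF against NF (484), 1773 for BiV-HF against NF (1083) and 66 for BiV-HF against LV-HF (0). For RV against LV it called 3 in NF, 10 in LV-HF and 7 in BiV-HF (edgeR 0 in each), and 1 for the interaction of LV-HF and NF (0). Upper-quartile scaling gave 25 for BiV-HF against LV-HF in the RV. No filter gave 3 and a CPM of at least 5 gave 3 for RV against LV in BiV-HF. In the fit of all 30 libraries 0 genes were called for BiV-HF against LV-HF in the RV. The 10 libraries compared gave 801 for BiV-HF against NF and 36 for BiV-HF against LV-HF in the RV, and 317 for LV-HF and 404 for BiV-HF against NF in the LV.

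Limma on log2(FPKM + 1) called 209 for BiV-HF against NF, 122 for LV-HF against NF and 1 for BiV-HF against LV-HF in the RV, and 35 for LV-HF and 68 for BiV-HF against NF in the LV. Without NF RV libraries 3 and 4 edgeR called 669 for BiV-HF and 320 for LV-HF against NF.

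The replicate block gave 864 (BiV-HF against NF), 516 (LV-HF against NF) and 1 (BiV-HF against LV-HF) in the RV and 641 (BiV-HF against NF) in the LV. Across heart states the block joins unrelated hearts, as equal numbers had a median r of -0.0435 there, and a lost call under it is no measure of the effect. For RV against LV, where the pairs are real, it gave 46 called genes in NF and 0 in LV-HF and BiV-HF, and 0 in both interactions. Counts at an unadjusted p under 0.05 rose with it from 857 to 2185 in NF, 586 to 1785 in LV-HF and 588 to 1652 in BiV-HF. For the interactions they rose from 335 to 1187 (BiV-HF and LV-HF) and from 210 to 798 (LV-HF and NF).

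With each library left out, BiV-HF against NF in the RV ran from 835 (without BiV-HF RV 2) to 1563 (without BiV-HF RV 5), with 872 without BiV-HF RV 3. LV-HF against NF in the RV ran from 520 (without LV-HF RV 2) to 1190 (without NF RV 2), with 552, 530, 614 and 529 without LV-HF RV 4, LV-HF RV 5, NF RV 1 and NF RV 3. BiV-HF against LV-HF in the RV ran from 0 (without BiV-HF RV 2 or 3, LV-HF RV 2 or 5) to 20 (without BiV-HF RV 4), with 19 without LV-HF RV 4, 2 without BiV-HF RV 1 or LV-HF RV 3 and 1 without LV-HF RV 1. LV-HF against NF in the LV ran from 248 (without LV-HF LV 3) to 605 (without NF LV 3), with 306 and 312 without LV-HF LV 2 and 4. BiV-HF against NF in the LV ran from 416 (without BiV-HF LV 1) to 1419 (without NF LV 3), with 570, 571 and 601 without BiV-HF LV 2, NF LV 2 and NF LV 4. Ranges were 0 to 1 for BiV-HF against LV-HF in the LV (1 without LV-HF LV 3), 0 to 2 for RV against LV in BiV-HF (2 without BiV-HF LV 1) and 0 to 1 for the interaction of LV-HF and NF (1 without NF LV 5).

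Of 475 list tests camera called 170, 0 with an estimated correlation, and fry 47, of which 42 were shared. WIPI1 co-variation gave 1 relation without removing group means, and 0 to 1 with a library left out (1 without LV-HF RV 1). For WIPI1 itself, the log2 ratio of BiV-HF to LV-HF in the RV ran from 0.35 to 0.53 with a library left out, and that of RV to LV in BiV-HF from 0.27 to 0.45. Without BiV-HF RV 2 the adjusted p of each was 0.0357 in the exact permutation test, with ranges over all alternatives of 0.0357 to 0.357 and 0.0357 to 0.375. For the WIPI1 difference within hearts, BiV-HF against NF ran from 0.55 to 0.71 and BiV-HF against LV-HF from 0.31 to 0.59 over the scalings, FPKM and hearts left out. Their adjusted p over 12 tests ran from 0.0952 to 0.0952 and from 0.0952 to 0.171, and over 3 tests from 0.0238 to 0.0238 and from 0.0238 to 0.0714. The alternative pseudocount and the other settings for FPKM were not run, since counts were used. Of simulated 2-fold changes 54 of 97 were found for BiV-HF against LV-HF in the RV, so a change of that size can be missed there. Whether depth, group size or variation between hearts sets this was not separated.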

Other observations

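The short-locus and SNORD values, the single immediate-early genes and the loci without a name were chosen only after the result was seen, and the splits of the samples before. SNORD genes encode small nucleolar RNAs, which guide the modification of ribosomal RNA and carry no poly(A) tail. The sum of 12 SNORD loci was 59.0 ± 59.2 CPM (SD, n = 5) in NF RV, 15.6 ± 5.45 in LV-HF RV, 18.0 ± 4.06 in BiV-HF RV, 63.9 ± 15.7 in NF LV, 81.7 ± 10.6 in LV-HF LV and 88.0 ± 27.9 in BiV-HF LV. It was higher in the RV than in the LV of the same heart in 1 of 15 hearts, and in 0 of 10 failing hearts. In failing hearts 11 of 12 SNORD loci were lower in the RV (median log2 difference -2.20). The table gives these 12 loci spans of 115 to 80073 bp, with 1 under 300 bp, so the RNA behind their fragments is not resolved. The 6 loci under 300 bp with other names were all lower in the RV (median -1.23), while 13 loci whose span includes that of a SNORD locus had a median of -0.03.

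Of 10 immediate-early genes looked at singly, which stimulated cells transcribe within minutes, FOS, FOSB and DUSP1 were higher in the RV in the most hearts (14 of 15 each) and ATF3 in the fewest (7 of 15). The adipocyte genes ADIPOQ and PLIN1 were higher in the RV in 11 and 12 of 15 hearts. MALAT1 was higher in the RV in 8 and NEAT1 in 11 of 15 hearts. By state these were 4 of 5 NF, 0 of 5 LV-HF and 4 of 5 BiV-HF hearts for MALAT1. For NEAT1 they were 5, 3 and 3 of 5. Fragments of 1756 of the 1801 loci without a gene name, not used in the comparisons, made up a mean of 0.387% in BiV-HF LV (exact p = 0.0317, adjusted p = 0.127) and 0.41% in LV-HF LV (exact p = 0.143, adjusted p = 0.19) against 0.49% in NF LV, where 1 library had 0.708%. In the RV they made up 0.422% in BiV-HF (exact p = 0.429, adjusted p = 0.429) and 0.407% in LV-HF (exact p = 0.0635, adjusted p = 0.127) against 0.447% in NF, so 0 of 4 tests passed after adjustment.

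Other splits of the libraries into groups of the same sizes were counted, 100 for each comparison with the real one included. The bar set beforehand was that under 5% of the splits give as many. The bar was met, which argues against chance, for the calls of BiV-HF against NF in the RV (1362, highest other 216, 1 split as large) and LV-HF against NF in the RV (971, highest other 2, 1 split). It was likewise met for LV-HF against NF in the LV (484, highest other 6, 1 split) and BiV-HF against NF in the LV (1083, highest other 578, 1 split). A share of 1 in 100 is the smallest that these draws can give. No other split drawn gave as many in these. The calls of BiV-HF against LV-HF in the RV also met the bar (8, highest other 29, 2 splits). Another split gave more calls there, so chance is not excluded. For genes at an unadjusted p under 0.05 the bar was met for BiV-HF against LV-HF in the LV (1389, highest other 1645, 3 splits) and the interaction of BiV-HF and LV-HF (335, highest other 361, 3 splits). In both edgeR called 0 genes (DESeq2 66 and 0) and other splits gave more than the real one, so chance is not excluded for these counts. The 335 of 13751 genes are under 5%, but that fit ignored the pairs of RV and LV. Its other splits had a median of 95, so 5% is not its rate without an effect. The count alone thus shows neither an effect nor its absence. With the heart as a block the count was 1187, for which no splits were run. The interaction of LV-HF and NF did not meet the bar (210, highest other 386, 20 splits), so chance cannot be excluded for it either. The shares of splits are not adjusted over the comparisons. For BiV-HF against LV-HF in the RV the split with 29 calls, over 3 times the real count, points to a structure of the samples, and the 8 calls fell to 0 without BiV-HF RV 2, BiV-HF RV 3, LV-HF RV 2 or LV-HF RV 5. For RV against LV the real counts were 857 in NF (highest other 3206, 75 splits), 586 in LV-HF (highest other 1084, 29 splits) and 588 in BiV-HF (highest other 2334, 43 splits). Those high counts point to a structure of the samples, since splits that keep the libraries of a heart together set hearts against each other. Among the splits drawn that part all 5 pairs, as the real one does, the highest others were 657, 575 and 484. With the heart as a block, swaps of RV and LV in NF hearts gave 46 calls for the real assignment and at most 1 for the others, 1 of 16 as large. Genes at an unadjusted p under 0.05 were then 2185 in NF (highest other 1970), 1785 in LV-HF (highest other 1801) and 1652 in BiV-HF (highest other 1600). With 5 hearts 16 swaps exist, too few for a share under 0.05.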
